A study of Pseudideonella sakaiensis with 3 samples.

How the data were processed

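RNA was sequenced from wild-type Ideonella sakaiensis 201-F6 after 20 h in YSV medium with PET film, disodium terephthalate (TPA) or ethylene glycol (EG) as the main carbon source, 1 library each. Per the labels' protocols, total RNA was purified on columns with DNase digestion, and 16S and 23S ribosomal RNA were removed with a Ribo-Zero kit before library preparation. Grouping followed the sample titles. The values are a whole-number score per gene and library that, per the file headers, is an RPKM made by the authors, and all 16587 values were whole numbers, so they were treated as RPKM rounded by the authors and not as counts. The aligner, counting tool, genome build and annotation version are not given in the sources used here. Whether reads were counted by strand is not given either, so reads of overlapping genes or antisense transcripts cannot be told apart. How reads shared between near-identical genes were counted is also not given. An RPKM divides by the total of its library, so a few very abundant transcripts lower the values of all others in that library.

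The table held 5529 gene rows with consecutive locus numbers and 2136 blank rows, which were left out. No tRNA or ribosomal RNA genes were among them. Gene positions are therefore given as locus tags, and genome coordinates were not used here. Without counts or gene lengths the depth of each library is unknown, and no interval was computed from it. Rounding to whole RPKM limits the precision by up to 0.5 RPKM. The half-width this gives a log2 ratio had a median of 0.021 and a 95th percentile of 0.10 over the genes kept, and was at most 0.27 among the genes chosen by the naming rule.

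Ratios between 2 libraries were computed as log2(RPKM + 1) of the first minus that of the second, so that the fold of low genes is understated. Genes with a mean of at least 10 RPKM over the 3 libraries were kept, which left 4868 genes and removed 661. The comparisons were PET against TPA, PET against EG and EG against TPA. With 1 library per carbon source no test was run and no p-value or standard error is given. Genes were counted at 4-fold, and members of gene lists at 2-fold. Runs of at least 3 consecutive genes past 4-fold in one direction were set beside 1000 shuffles of the gene order. Genes 4-fold above or below both other libraries were counted, and set beside the overlap of independent lists and beside 100 simulated unchanged profiles whose noise SD came from the central spread of the ratios.

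Before the data were examined, 25 gene lists were fixed by locus tag and by words in the product names, a gene counting in the first list it matched. They were PET hydrolysis, terephthalate catabolism, protocatechuate ring cleavage and beta-ketoadipate pathway, other aromatic catabolism, PQQ and quinoprotein alcohol oxidation, other alcohol dehydrogenases, aldehyde dehydrogenases, glycolate and glyoxylate metabolism, TCA cycle, respiratory chain and ATP synthase, gluconeogenesis and lower glycolysis, PHA and acetyl-CoA storage, fatty acid beta-oxidation, ribosomal proteins, flagella and chemotaxis, type IV pili and fimbriae, protein secretion, chaperones and heat shock, oxidative stress, iron uptake and TonB receptors, nitrogen assimilation, tripartite tricarboxylate and TRAP transport, CO2 fixation and formate oxidation, mobile elements and phage, and structural RNA. The structural RNA list had 0 members. Product names that matched a word by accident were removed from the lists after the table was opened, from the names alone, and the lists with all matches were an added alternative. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched in 10 bins of mean expression. That percentile describes these libraries. The random lists draw genes singly, while members of a list can be neighbours transcribed together, so a percentile can look too extreme. A further 12 lists were chosen after the values were seen and appear in the closing section only.

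The rule for naming genes was also fixed beforehand. It took all members of the PET hydrolysis and terephthalate catabolism lists and up to 4 members of each other list with the largest absolute log2 ratio in any comparison. For each comparison it took the 10 highest and 10 lowest genes with a product name, the highest and lowest hypothetical gene and the 3 longest runs, and for each library the 5 most abundant genes. It gave 150 genes, of which the members of long runs are summarised.

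The alternatives were pseudocounts of 0.1 and 10, no filter, a minimum mean of 50 RPKM, rescaling of the libraries by median of ratios over genes above 0 in all of them, rescaling to the sum without the 20 most abundant genes of any library, and a 2-fold threshold. The calculations were first tested on simulated data with genes 8-fold apart and a noise SD of 0.3 log2 units. For PET against TPA 97.9% of 193 such genes were recovered, for PET against EG 98.0% of 197 and for EG against TPA 99.0% of 194, with 0 unchanged genes past 4-fold. A count near 0 was set beforehand by that noise SD. Counting error at low RPKM and variation between cultures were not simulated, so this checks the calculations only. Of the genes placed in runs, 30 of 38, 28 of 36 and 20 of 31 were found in runs, so counts of genes in runs can be underestimates. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.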

Results

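Ideonella sakaiensis 201-F6 is a bacterium known for using poly(ethylene terephthalate) (PET), the polyester of drink bottles, as a carbon source. PET is hydrolysed outside the cell and releases terephthalic acid (TPA), an aromatic diacid, and ethylene glycol (EG), a short diol. Transcript levels of wild-type cells were measured by RNA sequencing after 20 h on PET film, on disodium terephthalate or on ethylene glycol. There was 1 library for each of the 3 carbon sources (n = 1 each), so no difference described here has a replicate check, and all values describe these libraries. The table held 5529 genes, given as locus tags with a product name and an RPKM, a read density scaled to gene length and to library size. The read depth of the libraries is unknown. The median RPKM per gene was 59 on PET, 58 on TPA and 54 on EG. The RPKM values of each library summed to 904838, 898680 and 932956, and the 20 most abundant genes held 14.2%, 17.4% and 16.8% of these sums.

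The most abundant transcripts overlapped between the libraries. A hypothetical protein gene, ISF6_1126, was the most abundant in each, at 20750 RPKM on PET, 19723 on TPA and 20676 on EG. An outer membrane porin gene (ISF6_0271) was also among the 5 most abundant in each, at 9724, 10520 and 12052 RPKM. The other genes among the 5 most abundant differed by carbon source. On PET they were an aldehyde dehydrogenase gene (ISF6_0529, 10672 RPKM), a porin gene (ISF6_1504, 8061 RPKM) and the hypothetical gene ISF6_0528 (7515 RPKM). On TPA they were ISF6_4831, the gene of the PET hydrolase PETase (annotated as a lipase, 18859 RPKM), the type IV pilin gene pilA (ISF6_2284, 15944 RPKM) and ISF6_0224 (9599 RPKM). ISF6_0224 encodes MHETase, which splits mono(2-hydroxyethyl) terephthalate and is annotated as a chlorogenate esterase. On EG they were pilA (15805 RPKM), the aldehyde dehydrogenase gene (12200 RPKM) and the PETase gene (11735 RPKM).

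The first comparison set growth on the polymer against growth on its aromatic monomer. On PET, the genes for breaking down terephthalate were lower than on TPA but still abundant, while 7 of 14 PQQ and quinoprotein genes of alcohol oxidation and 2 of 13 glycolate and glyoxylate genes were at least 2-fold higher. Most genes for flagella and chemotaxis and a run of benzoate breakdown genes were lower on PET. Of 4868 genes with a mean RPKM of at least 10, 61 were at least 4-fold higher on PET than on TPA and 84 were at least 4-fold lower, with folds taken on the log2(RPKM + 1) scale. Of these, 20 of the higher and 12 of the lower genes were hypothetical, as were 1218 of all 4868 genes. Values lay within 2-fold for 89.9% of genes, and the median log2 ratio over all of them was 0.10.

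The PETase gene (ISF6_4831) reached 4813 RPKM on PET and 18859 RPKM on TPA, a log2 ratio of -1.97, and the MHETase gene (ISF6_0224) 983 and 9599 RPKM, a log2 ratio of -3.29. The list of PET hydrolysis genes also held 2 genes annotated as tannase and feruloyl esterase, ISF6_2370 (16 and 26 RPKM) and ISF6_5003 (14 and 13 RPKM). The median of these 4 genes was -1.32, at percentile 0.21 among 10000 random lists matched on mean expression, and it was -2.63 with the mean RPKM filter at 50, which keeps PETase and MHETase alone. Each of the 4 genes of terephthalate catabolism was at least 2-fold lower on PET. These were the terephthalate dioxygenase large and small subunit genes ISF6_0227 (2064 and 9324 RPKM, log2 ratio -2.17) and ISF6_0228 (1603 and 6836 RPKM, log2 ratio -2.09), the dihydrodiol dehydrogenase gene ISF6_0229 (1239 and 3698 RPKM, log2 ratio -1.58) and the dioxygenase reductase gene ISF6_0230 (759 and 3186 RPKM, log2 ratio -2.07). Their names come from general knowledge of this organism, since the table carries names of related enzymes, such as ortho-halobenzoate dioxygenase subunits for ISF6_0227 and ISF6_0228. The list median was -2.08, at percentile 0.12.

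Genes for the later steps of terephthalate breakdown and for other aromatic compounds differed less evenly. Of 18 genes of protocatechuate cleavage and the beta-ketoadipate route, 2 were at least 2-fold lower and 1 at least 2-fold higher, with a list median of -0.20 at percentile 1.46. The 2 lower genes were those of the protocatechuate 3,4-dioxygenase alpha and beta chains, ISF6_0626 (531 and 1065 RPKM, log2 ratio -1.0) and ISF6_0627 (759 and 1562 RPKM, log2 ratio -1.04). Of 30 other aromatic catabolism genes, 16 were at least 2-fold lower on PET and none was 2-fold higher. Their median was -1.20, below every random list, and it was -0.52 without the filter on low values and -0.44 with all names that matched the fixed words. The lowest, benzoate-CoA ligase, was in a run of 9 neighbouring genes, ISF6_2816 to ISF6_2824, with a median of -3.39. That run held genes of the benzoyl-CoA (box) pathway, which activates benzoate with coenzyme A before the ring is opened. Its members ISF6_2818 and ISF6_2821 to ISF6_2824 are not in the list of other aromatic catabolism genes. Benzoate-CoA ligase (ISF6_2817) was at 91 RPKM on PET and 1410 on TPA, benzaldehyde dehydrogenase (ISF6_2818) at 79 and 1275, the lyase BoxC (ISF6_2821) at 89 and 1356, and benzoyl-CoA oxygenase component B (ISF6_2822) at 191 and 2966.

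Part of the alcohol oxidation genes were higher on PET than on TPA. Pyrroloquinoline quinone (PQQ) is the cofactor of periplasmic alcohol dehydrogenases that pass electrons to cytochrome c. Of 14 PQQ and quinoprotein genes, 7 were at least 2-fold higher on PET and none was 2-fold lower, with a list median of 0.83 above every random list, or 1.45 with the filter at a mean RPKM of 50. Cytochrome c550 (ISF6_4629) was at 4538 RPKM on PET and 126 on TPA, a log2 ratio of 5.16. The quinoprotein alcohol dehydrogenase ISF6_2768 was at 4953 and 336 RPKM (3.88), the associated cytochrome c550 ISF6_2770 at 1882 and 97 RPKM (4.26) and the PQQ synthesis protein B gene ISF6_4626 at 734 and 50 RPKM (3.85). Of 10 aldehyde dehydrogenase genes, 1 was at least 2-fold higher, ISF6_0529 at 10672 and 628 RPKM (4.08), and 1 at least 2-fold lower, the benzaldehyde dehydrogenase named above. The median of that list was -0.27 at percentile 1.99. The 5 other alcohol dehydrogenase genes lay within 2-fold (median -0.30, percentile 7.22), among them ISF6_2301 at 59 and 83 RPKM and ISF6_4201 at 38 and 51 RPKM.

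A few genes of glyoxylate use and respiration were at least 2-fold higher on PET, and most members of these lists lay within 2-fold. Isocitrate lyase (ISF6_5405) was at 1884 RPKM on PET and 113 on TPA (log2 ratio 4.05), and malate synthase G (ISF6_5157) at 457 and 65 RPKM (2.79). They were the only 2 of 13 glycolate and glyoxylate genes past 2-fold, and the list median was 0.56 at percentile 99.98. The glycolate dehydrogenase subunits GlcD (ISF6_0605, 308 and 164 RPKM) and GlcE (ISF6_0606, 172 and 92 RPKM) had log2 ratios of 0.91 and 0.90. Of 44 respiratory chain and ATP synthase genes, 4 were at least 2-fold higher and none 2-fold lower (median 0.50, above every random list). Among them were cytochrome o ubiquinol oxidase subunits II (ISF6_1235, 76 and 16 RPKM) and III (ISF6_1237, 68 and 15 RPKM), with log2 ratios of 2.18 and 2.11. Aconitate hydratase 2 (ISF6_2434, 729 and 313 RPKM, 1.22) was the 1 gene of 21 in the TCA cycle list past 2-fold (median 0.37, percentile 99.22). None of 20 gluconeogenesis and lower glycolysis genes passed 2-fold (median 0.37, percentile 99.45), with phosphoenolpyruvate carboxykinase (ISF6_2330, 548 and 291 RPKM) at 0.91. Of 25 nitrogen assimilation genes, 5 were at least 2-fold higher (median 0.40, percentile 99.99), including an ammonium transporter (ISF6_1785, 116 and 33 RPKM, 1.78) and the regulator P-II (ISF6_1786, 155 and 52 RPKM, 1.56).

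Motility genes were low on PET as a group. Of 75 flagella and chemotaxis genes, 69 were at least 2-fold lower on PET, 24 at least 4-fold lower and none 2-fold higher. The list median was -1.84, below every random list. Examples were methyl-accepting chemotaxis proteins ISF6_4470 (75 and 761 RPKM, log2 ratio -3.33) and ISF6_1922 (12 and 104 RPKM, -3.01) and the methyltransferase CheR (ISF6_2070, 8 and 66 RPKM, -2.90). Type IV pilus genes did not share this difference, since 1 of 31 was 2-fold lower (median 0.02, percentile 8.99). That gene was the pilin pilA (ISF6_2284, 5481 and 15944 RPKM, -1.54). Formate dehydrogenase genes were also low on PET, with the alpha subunit (ISF6_3288) at 17 and 352 RPKM (-4.29) and the beta subunit (ISF6_3287) at 16 RPKM on PET (-3.72). In their list of 28 CO2 fixation and formate oxidation genes, 8 were at least 2-fold lower and 4 at least 2-fold higher (median -0.08, percentile 5.29, or -0.96 with the filter at a mean RPKM of 50). The highest was a gene named for carbon monoxide dehydrogenase (ISF6_2774, 617 and 68 RPKM, 3.16), not for formate oxidation. Of 45 tripartite transporter genes 5 were 2-fold lower (median -0.16, percentile 0.14), the lowest being TctA (ISF6_4527, 99 and 1113 RPKM, -3.48) and TctB (ISF6_4528, 173 and 1668 RPKM, -3.26).

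In the other lists most genes lay within 2-fold. Of 66 fatty acid beta-oxidation genes, 9 were at least 2-fold lower and 1 higher (median -0.28, below every random list), with a long-chain acyl-CoA ligase (ISF6_4715, 20 and 89 RPKM) at -2.10. Of 9 polyhydroxyalkanoate (PHA) storage genes, 1 acetoacetyl-CoA reductase (ISF6_1331, 60 and 264 RPKM) was lower, at -2.12 (median -0.01, percentile 18.5). None of 54 ribosomal protein genes passed 2-fold (median 0.22, percentile 80.1), the highest being L20p (ISF6_3161, 6107 and 3987 RPKM) at 0.62. The same held for 30 protein secretion genes (median 0.16, percentile 65.5), 33 chaperone genes (0.09, percentile 23.9) and 17 mobile element genes (0.08, percentile 59.3). Catalase (ISF6_2780, 115 and 46 RPKM, 1.30) was the 1 of 26 oxidative stress genes past 2-fold (median 0.10, percentile 39.8). A TonB-dependent receptor (ISF6_0120, 732 and 1760 RPKM, -1.26) was the 1 of 28 iron uptake genes (median 0.15, percentile 72.1).

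Genes past 4-fold lay side by side. Of the 145 such genes, 87 were in 17 runs of at least 3 neighbours, against a mean of 0.089 genes in 1000 shuffles of the gene order. Neighbouring bacterial genes are often transcribed together, so in each comparison an excess over shuffles of single genes was set beforehand. The longest run held 13 genes, ISF6_2767 to ISF6_2779 (median 2.61), covering the quinoprotein dehydrogenase and genes annotated for carbon monoxide dehydrogenase, such as its small chain (ISF6_2779, 3482 and 618 RPKM). The next was 10 genes, ISF6_4617 to ISF6_4626 (median 2.87), ending in the PQQ synthesis protein B gene. The highest ratio among all genes was that of the hypothetical gene ISF6_2619 (2237 and 27 RPKM, 6.32), beside a probable transmembrane protein gene (ISF6_2618, 1364 and 32 RPKM, 5.37). Other genes among the 10 highest with a product name were a putative membrane protein (ISF6_0408, 573 and 16 RPKM), multidrug resistance protein B (ISF6_5009, 301 and 9 RPKM), an ABC transporter ATP-binding protein (ISF6_1140, 676 and 29 RPKM), NnrS (ISF6_1142, 471 and 22 RPKM), a cytochrome c (ISF6_1743, 979 and 43 RPKM), a UDP-N-acetylmuramate--alanine ligase (ISF6_1744, 744 and 28 RPKM) and a putative periplasmic binding protein (ISF6_4630, 1683 and 58 RPKM). Among the lowest was a branched-chain amino acid binding protein (ISF6_4711, 41 and 467 RPKM, -3.48), in the same run as the lowest hypothetical gene (ISF6_4709, 26 and 216 RPKM, -3.01).

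**Figure D1:**
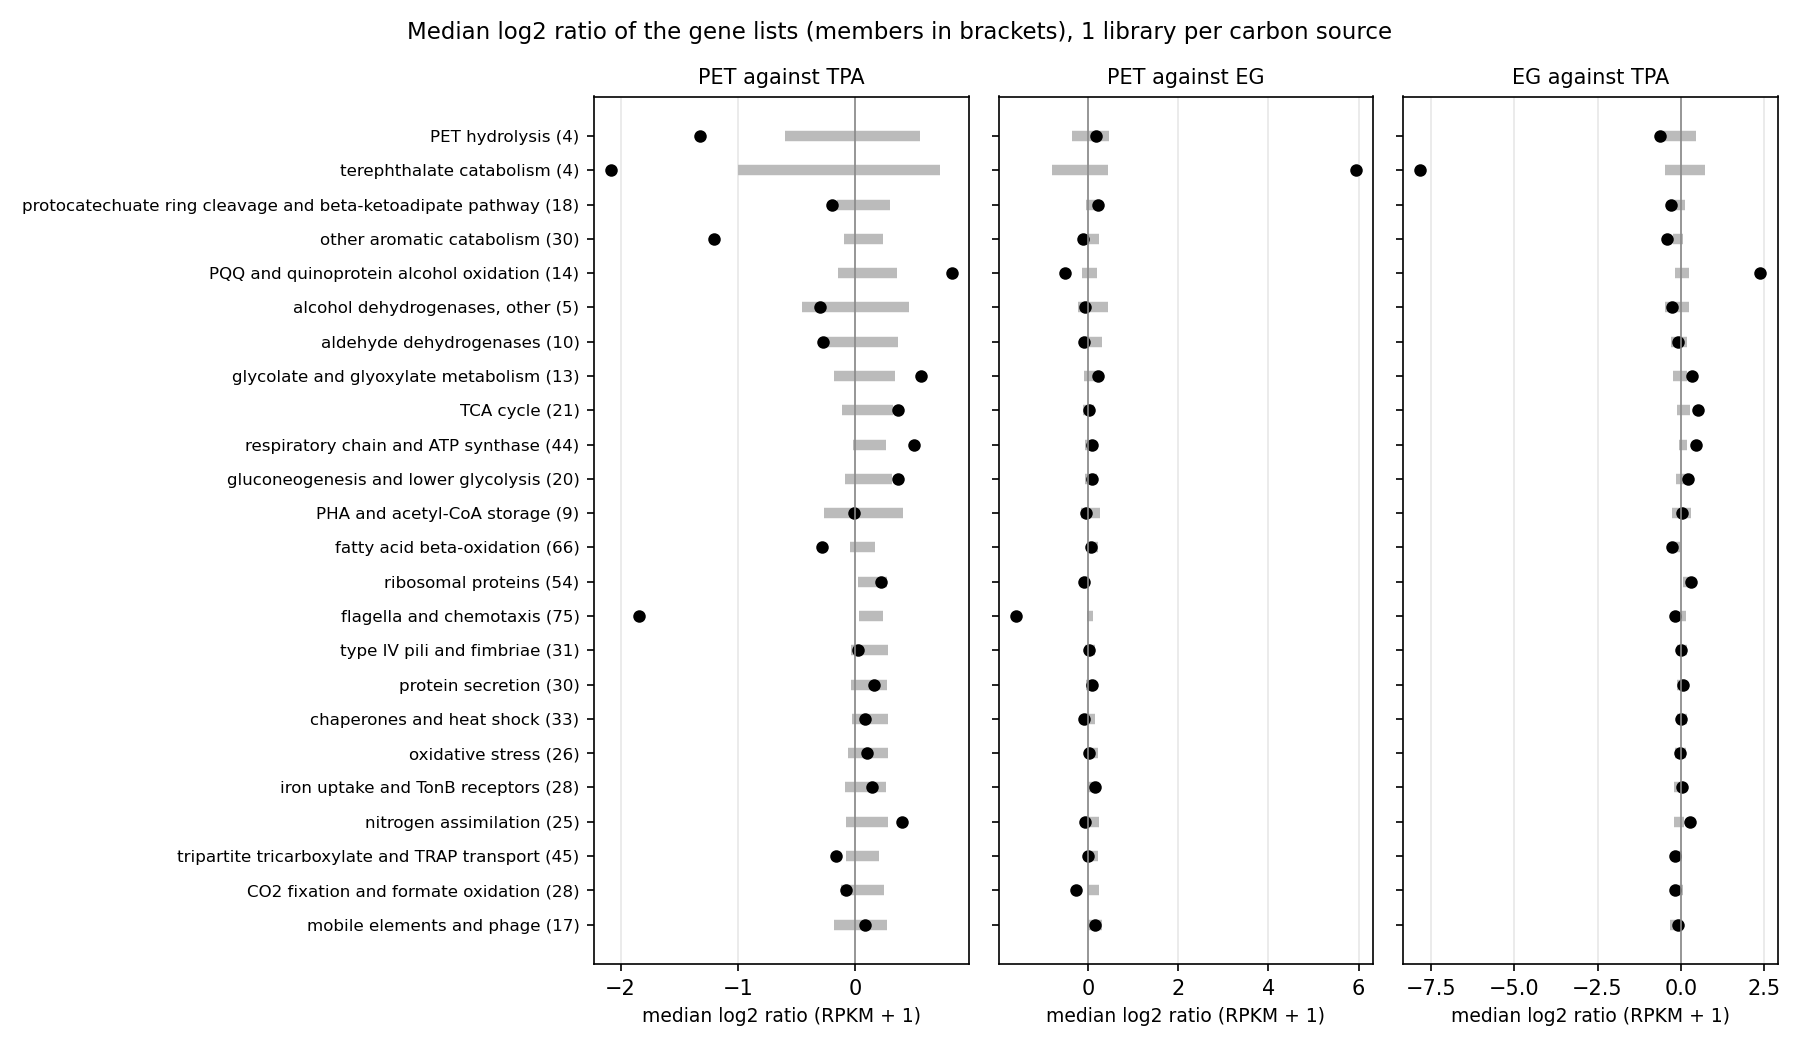
Median log2 ratio, on the log2(RPKM + 1) scale, of each gene list in the 3 comparisons, with 1 library per carbon source. Points are list medians, grey bars span the central 95% of medians of 10000 random lists matched on mean expression, the number of measured members is in brackets and the horizontal scales differ. The flagella and chemotaxis list lies at -1.84 for PET against TPA and at -1.60 for PET against EG, and the terephthalate list lies at 5.94 for PET against EG.

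The second comparison set the polymer against its diol. Here the terephthalate genes were far higher on PET than on EG, while 11 of 14 PQQ and quinoprotein genes were within 2-fold and 3 were at least 2-fold lower on PET. Flagella and chemotaxis genes were again lower on PET. Of the 4868 genes, 45 were at least 4-fold higher on PET than on EG and 27 at least 4-fold lower, and 92.5% lay within 2-fold. The median log2 ratio was 0.13. A rescaling of the libraries by median of ratios moved that median by -0.15 and gave 41 higher and 43 lower genes, so that 48.8% of the genes past 4-fold were higher in place of 62.5%.

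Each of the 4 terephthalate genes was at least 4-fold higher on PET than on EG, with a median of 5.94 above every random list. ISF6_0227 was at 2064 RPKM on PET and 34 on EG (5.88), ISF6_0228 at 1603 and 24 RPKM (6.0), ISF6_0229 at 1239 and 18 RPKM (6.03) and ISF6_0230 at 759 and 16 RPKM (5.48). They sat in the longest run of this comparison, 7 genes from ISF6_0226 to ISF6_0232 (median 5.88). Its first gene, a putative exported protein (ISF6_0226), had the highest ratio of the run, 2221 against 32 RPKM (6.07). The LysR-type regulator ISF6_0231 (625 and 24 RPKM, 4.65) and the hypothetical gene ISF6_0232 (54 and 4 RPKM, 3.46) closed it. Just outside lay the MHETase gene (ISF6_0224, 983 and 70 RPKM, 3.79) and a gene annotated as the regulator PcaR (ISF6_0223, 566 and 26 RPKM, 4.39). The PETase gene (ISF6_4831) was instead lower on PET, at 4813 against 11735 RPKM (-1.29). The PET hydrolysis list, with the low-abundance ISF6_2370 (16 and 17 RPKM) and ISF6_5003 (14 and 10 RPKM), had a median of 0.18 at percentile 75.3. With the mean RPKM filter at 50, which keeps PETase and MHETase alone, it was 1.25.

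Of the 18 protocatechuate and beta-ketoadipate genes, 5 were at least 2-fold higher on PET and none 2-fold lower (median 0.23, percentile 92.3). They included both protocatechuate 3,4-dioxygenase chains (ISF6_0626, 531 and 86 RPKM, 2.61; ISF6_0627, 759 and 131 RPKM, 2.53), 3-oxoadipate CoA-transferase subunit A (ISF6_4437, 289 and 102 RPKM, 1.49) and beta-ketoadipyl-CoA thiolase (ISF6_4439, 333 and 115 RPKM, 1.53). The list median was 1.49 with the filter at a mean RPKM of 50. Of the 30 other aromatic catabolism genes, 8 were at least 2-fold lower and 2 at least 2-fold higher (median -0.11, percentile 0.01). Phenylacetate-CoA ligase (ISF6_4708, 199 and 33 RPKM, 2.56) was one of the 2 higher. The benzoyl-CoA genes were low on PET here as well, in a run of 6 genes from ISF6_2817 to ISF6_2822 with a median of -3.48. BoxC (ISF6_2821) was at 89 RPKM on PET and 1982 on EG (-4.46), and the gene annotated as P-hydroxylaminobenzoate lyase (ISF6_2819) at 83 and 1569 RPKM (-4.22).

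Of the 14 PQQ and quinoprotein genes, 3 were at least 2-fold lower on PET than on EG and none 2-fold higher (median -0.50, percentile 0.01). The lowest was the methanol dehydrogenase large subunit gene (ISF6_1713) at -2.0, named after its values were seen. Cytochrome c550 (ISF6_4629) was at 4538 and 7708 RPKM (-0.76), and the quinoprotein dehydrogenase ISF6_2768 at 4953 and 6779 RPKM (-0.45). The aldehyde dehydrogenase ISF6_0529 lay at -0.19 and was within 2-fold, as were all but 1 of its list of 10 (median -0.09, percentile 3.18). None of the 13 glycolate and glyoxylate genes passed 2-fold (median 0.23, percentile 92.3), with isocitrate lyase at 0.50 and malate synthase G at 0.60. The 5 other alcohol dehydrogenase genes had a median of -0.07 at percentile 8.74, with ISF6_1729 (12 and 10 RPKM) at 0.24. In the CO2 fixation and formate list, 3 of 28 were 2-fold lower and none higher (median -0.27, below every random list), formate dehydrogenase alpha subunit (ISF6_3288, 17 and 77 RPKM) being at -2.12.

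Of the 75 flagella and chemotaxis genes, 67 were at least 2-fold lower on PET than on EG and 8 at least 4-fold lower, with none 2-fold higher (median -1.60, below every random list). The methyl-accepting chemotaxis protein ISF6_4470 was at 75 and 326 RPKM (-2.11), and ISF6_1922 at 12 and 49 RPKM (-1.94). Among 31 type IV pilus genes 2 were 2-fold lower (median 0.02, percentile 22.9), namely pilA (ISF6_2284, 5481 and 15805 RPKM, -1.53) and a PulE-type ATPase (ISF6_2751, 108 and 230 RPKM, -1.08). Of 45 tripartite transporter genes, 4 were 2-fold higher and 4 were 2-fold lower (median 0.00, percentile 0.46). TctA (ISF6_0077, 2510 and 337 RPKM, 2.89) and TctB (ISF6_0076, 2194 and 341 RPKM, 2.68) led the higher ones, and a TctC (ISF6_5076, 60 and 358 RPKM, -2.56) was the lowest. L-lactate permease (ISF6_1310, 16 and 436 RPKM, -4.68) and L-lactate dehydrogenase (ISF6_1311, 22 and 566 RPKM, -4.62) had the lowest ratios of this comparison.

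A few genes of carbon storage and central metabolism passed 2-fold. PHA synthase (ISF6_5039, 670 and 291 RPKM, 1.20) and an acetoacetyl-CoA reductase (ISF6_5037, 965 and 441 RPKM, 1.13) were the 2 of 9 storage genes past 2-fold (median -0.03, percentile 15.2). NADP-dependent malic enzyme (ISF6_5374, 230 and 58 RPKM, 1.97) was the 1 of 20 gluconeogenesis and glycolysis genes (median 0.09, percentile 64.6). The cytochrome c oxidase subunit CcoN (ISF6_0138, 183 and 69 RPKM, 1.39) was 1 of 3 of 44 respiratory genes 2-fold higher (median 0.10, percentile 93.6). A succinyl-CoA synthetase alpha subunit-related gene (ISF6_3279, 120 and 249 RPKM, -1.05) was the 1 TCA cycle gene past 2-fold (median 0.02, percentile 49.1). Of 66 beta-oxidation genes 2 were higher and 4 lower (median 0.07, percentile 0.76), an enoyl-CoA hydratase (ISF6_3136, 38 and 120 RPKM) being lowest at -1.63. Of 28 iron uptake genes 2 were lower (median 0.15, percentile 73.7), the TonB-dependent receptors ISF6_0976 (239 and 516 RPKM, -1.11) and ISF6_4432 (20 and 45 RPKM, -1.13). Of 25 nitrogen genes 1 was lower, a nitrate-binding protein (ISF6_2610, 11 and 23 RPKM, -1.0), with a median of -0.06 at percentile 0.41.

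No gene passed 2-fold among 54 ribosomal protein genes (median -0.08, percentile 17.4), 30 secretion genes (0.09, percentile 56.8), 33 chaperone genes (-0.09, percentile 0.48), 26 oxidative stress genes (0.02, percentile 12.4) and 17 mobile element genes (0.15, percentile 38.1). GroES (ISF6_0327) was the lowest chaperone gene, at 2252 RPKM on PET and 3257 on EG (-0.53). Of the 72 genes past 4-fold in this comparison, 27 lay in 6 runs, against a shuffled mean of 0.012. The third longest run, 5 genes from ISF6_1140 to ISF6_1144 (median 4.02), was higher on PET and began with the ABC transporter gene (ISF6_1140, 676 and 34 RPKM). Its other members were ISF6_1141 (305 and 17 RPKM), NnrS (ISF6_1142, 471 and 28 RPKM), a CysB-type activator (ISF6_1143, 116 and 16 RPKM) and ISF6_1144 (31 and 5 RPKM).

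The third comparison set the 2 monomers against each other. Terephthalate genes were far lower on EG than on TPA, and 9 of 14 PQQ and quinoprotein genes and 2 of 13 glycolate and glyoxylate genes were at least 2-fold higher on EG. Of the 4868 genes, 67 were at least 4-fold higher on EG than on TPA and 53 at least 4-fold lower, 93.7% lay within 2-fold and the median was -0.06. The 4 terephthalate genes had a median of -7.83 at percentile 0.005, with ISF6_0227 at 34 RPKM on EG and 9324 on TPA (-8.06), ISF6_0228 at 24 and 6836 (-8.10), ISF6_0229 at 18 and 3698 (-7.60) and ISF6_0230 at 16 and 3186 (-7.55). The 7 genes from ISF6_0226 to ISF6_0232 formed a run with a median of -7.60. The MHETase gene (ISF6_0224) was at 70 and 9599 RPKM (-7.08) and ISF6_0223 at 26 and 3971 RPKM (-7.20), whereas the PETase gene (ISF6_4831) was at 11735 and 18859 RPKM (-0.68). The median of the PET hydrolysis list was -0.63 at percentile 1.16, and -3.88 with the filter at a mean RPKM of 50.

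Of 18 protocatechuate genes 5 were at least 4-fold lower on EG and 1 was 2-fold higher (median -0.29, percentile 1.36), the lowest being ISF6_0626 (86 and 1065 RPKM, -3.62) and ISF6_0627 (131 and 1562 RPKM, -3.57). The median was -2.15 with the filter at a mean RPKM of 50. Of 30 other aromatic genes 9 were 2-fold lower and 1 higher (median -0.43, below every random list), with phenylacetate-CoA ligase (ISF6_4708) at 33 and 267 RPKM (-2.98). The benzoyl-CoA region went both ways between the monomers. ISF6_2818 (1085 and 1275 RPKM, -0.23) and ISF6_2821 (1982 and 1356 RPKM, 0.55) were within 2-fold, while benzoate-CoA ligase (ISF6_2817, 604 and 1410 RPKM) was at -1.22, benzoyl-CoA oxygenase component A (ISF6_2823, 532 and 2334 RPKM) at -2.13 and the ring-cleavage hydrolase ISF6_2816 (259 and 1309 RPKM) at -2.33. Tripartite transporter genes went both ways, 4 being 2-fold higher and 4 lower (median -0.18, percentile 5.53). TctA ISF6_4527 (24 and 1113 RPKM, -5.48) and TctB ISF6_4528 (36 and 1668 RPKM, -5.50) were the lowest, and TctC ISF6_5076 (358 and 55 RPKM, 2.68) the highest. The lowest hypothetical gene was ISF6_0559 (108 and 4950 RPKM, -5.51).

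On EG, 9 of 14 PQQ and quinoprotein genes were at least 2-fold higher than on TPA and 7 at least 4-fold higher, with none 2-fold lower (median 2.39, above every random list, or 1.56 with all names that matched the fixed words). Cytochrome c550 (ISF6_4629) was at 7708 and 126 RPKM (5.92), the quinoprotein dehydrogenase ISF6_2768 at 6779 and 336 RPKM (4.33) and the PQQ synthesis protein B gene ISF6_4626 at 943 and 50 RPKM (4.21). The highest hypothetical gene was ISF6_2769 (3643 and 185 RPKM, 4.29), between the dehydrogenase and its cytochrome. The aldehyde dehydrogenase ISF6_0529 was at 12200 and 628 RPKM (4.28) and alone of 10 in its list past 2-fold (median -0.08, percentile 43.1). The runs ISF6_2767 to ISF6_2779 and ISF6_4617 to ISF6_4626 were again the longest, with medians of 3.18 and 3.29, and 88 of the 120 genes past 4-fold lay in 19 runs, against a shuffled mean of 0.051. The carbon monoxide dehydrogenase small chain gene (ISF6_2779) was at 6804 and 618 RPKM (3.46), and L-lactate permease (ISF6_1310) at 436 and 13 RPKM (4.96).

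Isocitrate lyase (ISF6_5405, 1333 and 113 RPKM, 3.55) and malate synthase G (ISF6_5157, 301 and 65 RPKM, 2.19) were the 2 of 13 glyoxylate genes past 2-fold (median 0.33, percentile 99.98). Of 44 respiratory genes 10 were higher (median 0.47) and of 25 nitrogen genes 9 were (median 0.29), both medians above every random list, with P-II (ISF6_1786, 259 and 52 RPKM) at 2.29. The TCA cycle list had none past 2-fold and a median of 0.50 above every random list, malate dehydrogenase (ISF6_2428, 1141 and 662 RPKM) being at 0.78. Malic enzyme (ISF6_5374, 58 and 299 RPKM, -2.35) was the 1 of 20 gluconeogenesis genes past 2-fold (median 0.21, percentile 97.7). Of 9 storage genes 3 were lower and 1 higher (median 0.05, percentile 55.8), with PHA synthase at 291 and 829 RPKM (-1.51) and a PHA depolymerase (ISF6_3255, 44 and 15 RPKM) at 1.49. In the CO2 and formate list 4 were higher and 5 lower (median -0.17, percentile 15.2), formate dehydrogenase delta subunit (ISF6_3290, 4 and 70 RPKM) being at -3.83. Its highest member was again the gene named for carbon monoxide dehydrogenase (ISF6_2774, 842 and 68 RPKM, 3.61).

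Motility genes were close between the monomers, with 6 of 75 at least 2-fold lower on EG and none higher (median -0.16, below every random list), and ISF6_4470 was at -1.22. Of 66 beta-oxidation genes 2 were lower (median -0.27, percentile 0.015), with ISF6_4089 (110 and 309 RPKM) at -1.48. Of 28 iron uptake genes 2 were higher (median 0.02, percentile 85.1), with ISF6_4432 (45 and 15 RPKM) at 1.52. No member passed 2-fold among 54 ribosomal protein genes (median 0.30, percentile 99.5), 31 pilus genes (0.00, percentile 24.0), 30 secretion genes (0.05, percentile 70.2), 33 chaperone genes (0.00, percentile 28.4), 26 oxidative stress genes (-0.04, percentile 36.6), 17 mobile element genes (-0.09, percentile 69.2) and 5 other alcohol dehydrogenase genes (-0.27, percentile 17.9). GroES (ISF6_0327, 3257 and 1792 RPKM) was the highest chaperone gene at 0.86.

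**Figure D2:**
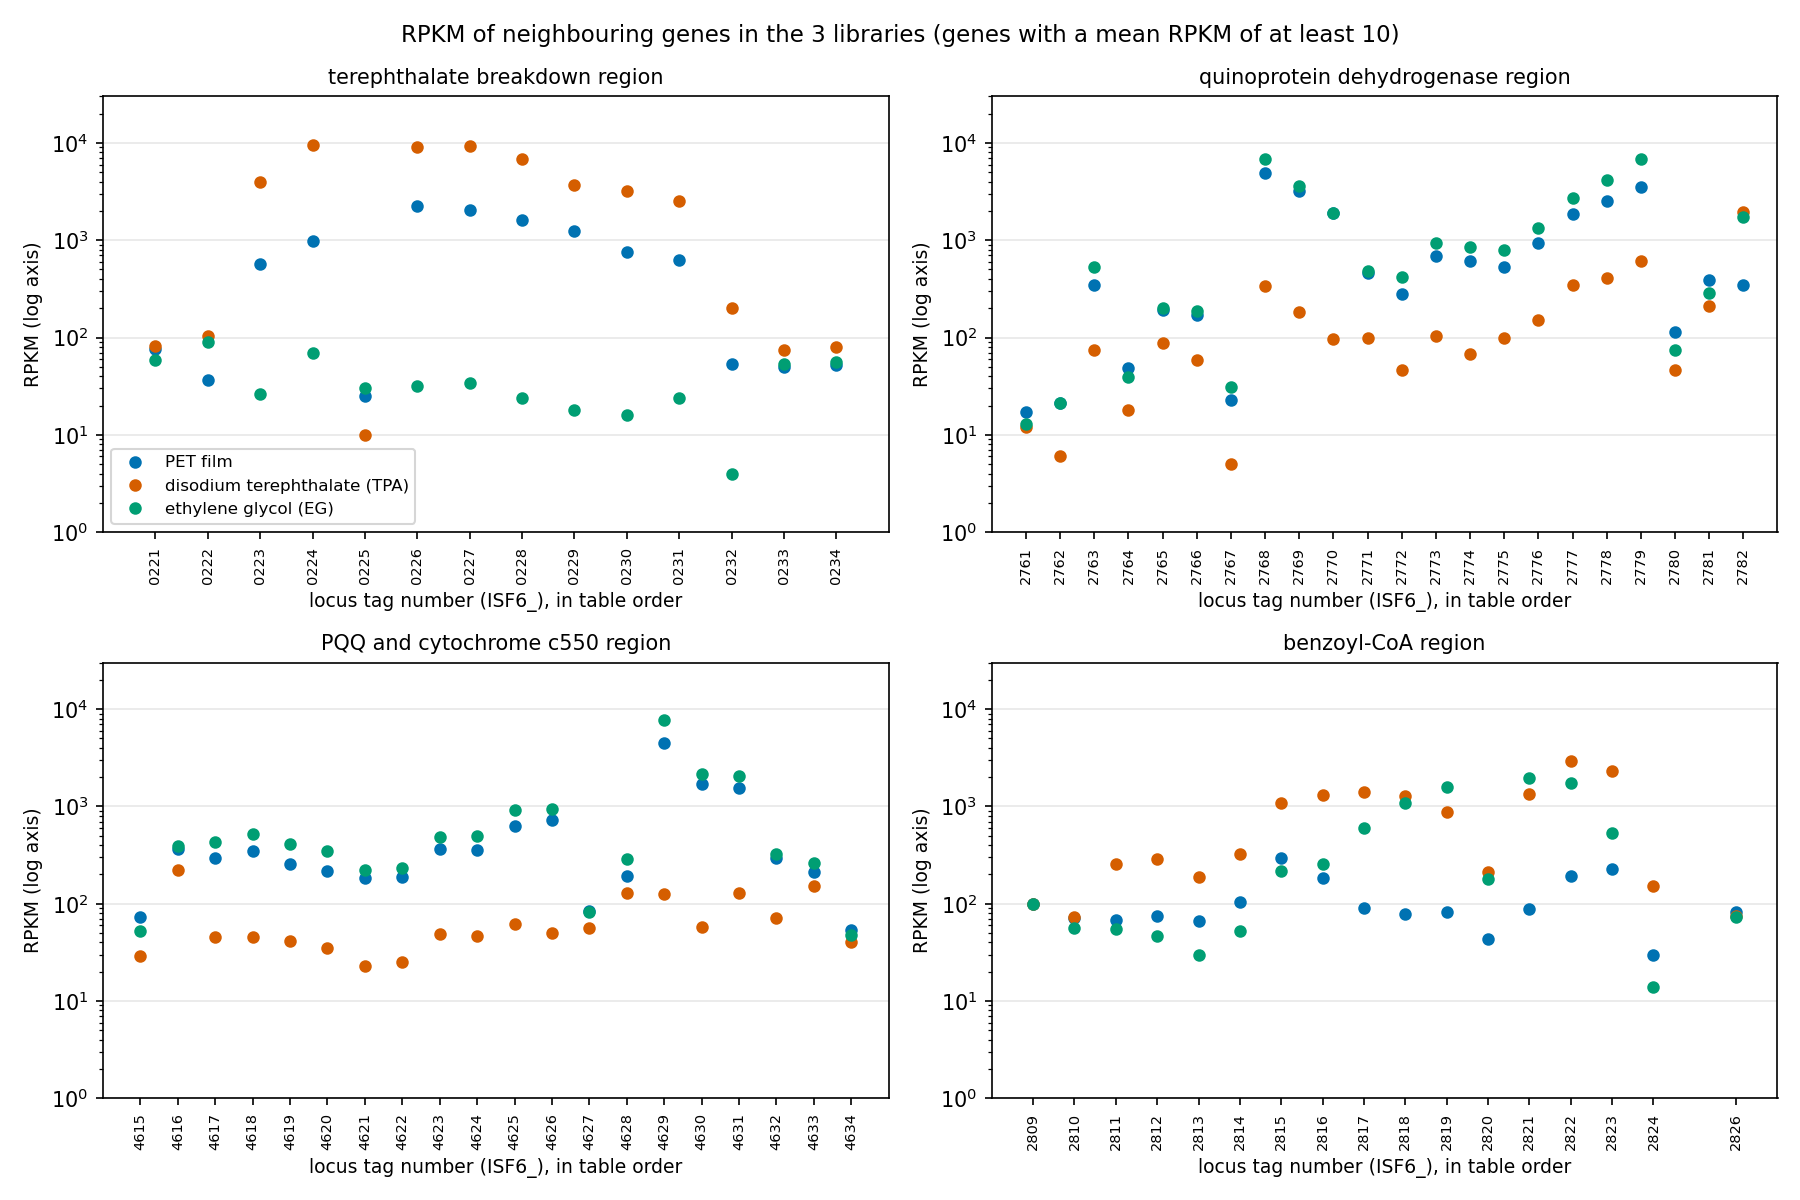
RPKM on a log axis of neighbouring genes, by locus tag number along the table, in 4 regions, with 1 point per gene and library for PET film, TPA and EG. Genes ISF6_0226 to ISF6_0231 are high on TPA, intermediate on PET and low on EG, ISF6_2767 to ISF6_2779 and ISF6_4617 to ISF6_4626 are low on TPA alone, and ISF6_2817 to ISF6_2822 are low on PET alone.

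The 3 comparisons together show where the PET library lay between those of its monomers. Of the 67 genes at least 4-fold higher on EG than on TPA, 38 were also at least 4-fold above TPA on PET and 43 lay within 2-fold of their EG level, while 12 lay within 2-fold of their TPA level and 9 were at least 4-fold below EG. Of the 53 genes at least 4-fold higher on TPA than on EG, 20 were at least 4-fold above EG on PET and 9 lay within 2-fold of their TPA level, while 20 lay within 2-fold of their EG level and 27 were at least 4-fold below TPA. From ISF6_0223 to ISF6_0232, leaving out the low ISF6_0225, the median PET level was 23.8% of the TPA level. Independent lists of these sizes would share 0.84 genes for the overlap of 38 and 0.49 for that of 20, but the overlaps share a library, so part of each can arise without a common effect.

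Genes 4-fold above or below both other libraries were counted for each library. On PET, 20 genes stood above both others, 6 of them hypothetical, and 17 below, or 28 below under median-of-ratios rescaling. Those above were in small neighbouring groups, such as ISF6_2618 and ISF6_2619, ISF6_1140 to ISF6_1144, and ISF6_1742 to ISF6_1744, except for the single genes ISF6_3641 and ISF6_5440. Those below included 6 benzoyl-CoA region genes, the flagellin FlaA (ISF6_4411, 795 RPKM on PET, 4670 on TPA and 3608 on EG) and the chemotaxis phosphatase CheZ (ISF6_3482, 197, 889 and 797 RPKM), the last 2 named after their values were seen. On TPA, 27 genes stood above both others and 38 below, the latter including ISF6_0529, the run from ISF6_2767 and isocitrate lyase. On EG, 9 genes stood above both, among them the lactate genes ISF6_1310 and ISF6_1311, and 20 below, among them the terephthalate genes. Independent lists of these sizes would share between 0.37 and 0.91 genes, which leaves out that the 2 ratios behind each count share a library. Simulated unchanged profiles that share it, with a noise SD of 0.27 log2 units, gave 0 genes, but 4-fold lies so far outside that noise that a count near 0 was set beforehand. Neither value measures the variation between cultures.

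**Figure D3:**
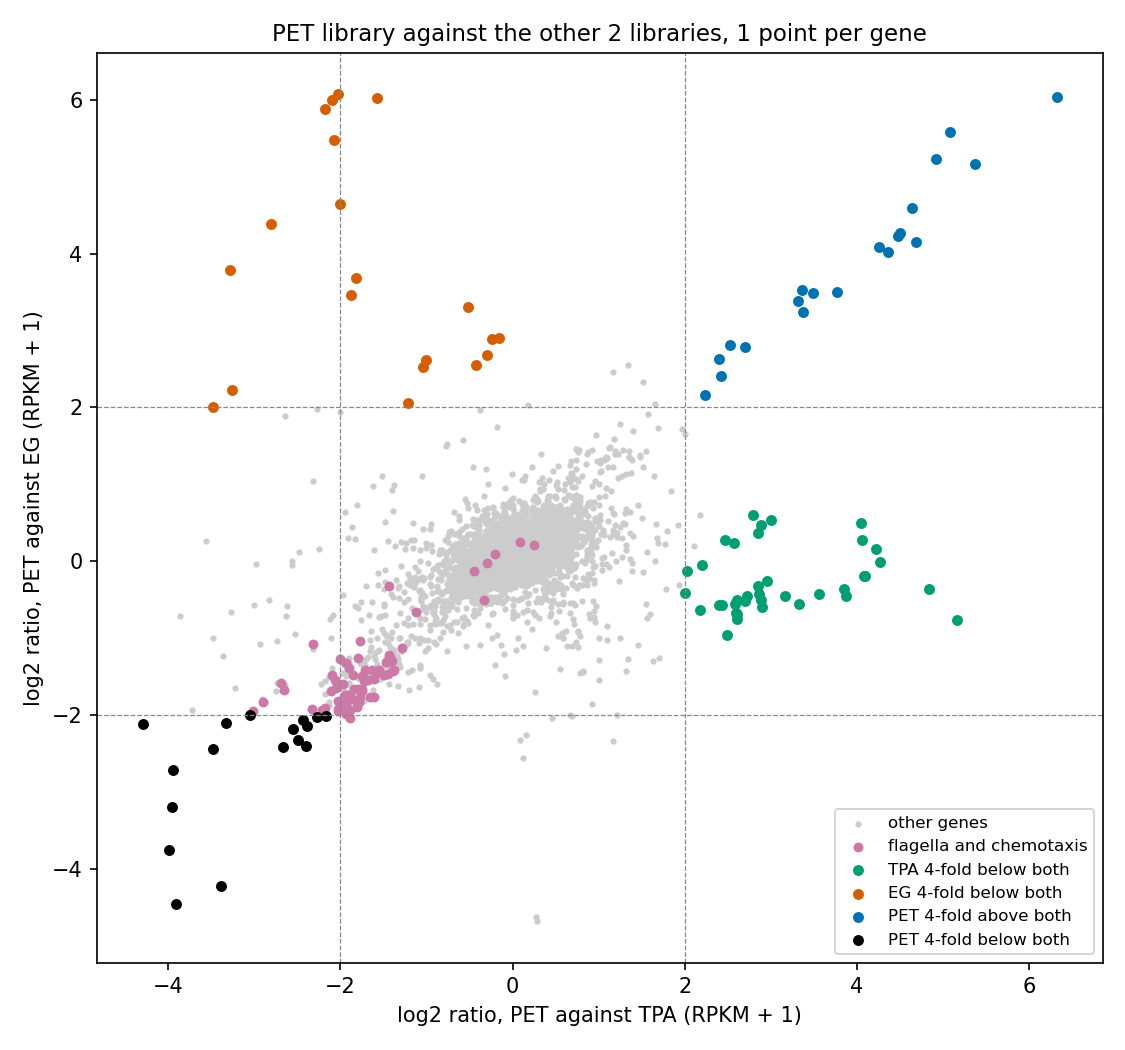
Log2 ratio of PET against TPA (horizontal) and of PET against EG (vertical), on the log2(RPKM + 1) scale, with 1 point for each of 4868 genes and dashed lines at 4-fold. Colours mark genes 4-fold above or below both others on PET, genes 4-fold below both others on TPA or on EG, and the flagella and chemotaxis list. Members of that list also 4-fold below both on PET are black. Genes 4-fold above both others on TPA or on EG have no colour of their own. Both axes share the PET library. The 20 genes above both on PET lie at the upper right and the 17 below both (28 under median-of-ratios rescaling, not drawn) at the lower left.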

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

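Without replicates or counts, a log2 value was regarded as moved when an alternative shifted it by at least 1.5-fold, and a count when it differed by more than 1.5 times. No paired analysis was possible because there is 1 library per carbon source. Apart from the 2-fold threshold, the counts of genes past 4-fold stayed within 1.5 times, with 1 exception. Under median-of-ratios rescaling 43 genes were at least 4-fold lower on PET than on EG in place of 27, all 27 among them, and 28 genes lay below both other libraries on PET in place of 17; this rescaling lowers the PET library relative to EG. Over the alternatives other than the threshold the counts were 54 to 62 higher and 65 to 98 lower for PET against TPA, 35 to 45 higher and 18 to 43 lower for PET against EG, and 55 to 70 higher and 49 to 54 lower for EG against TPA. At 2-fold they were 176 and 318, 131 and 233, and 158 and 148, since a lower threshold admits more genes, and the genes in runs were 295, 209 and 189.

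Of 504 values of list medians, 10 moved and 0 changed sign beyond 1.5-fold. With the filter at a mean of 50 RPKM, which keeps fewer members, the PET hydrolysis medians were -2.63 (PET against TPA), 1.25 (PET against EG) and -3.88 (EG against TPA). The protocatechuate medians were 1.49 (PET against EG) and -2.15 (EG against TPA), and for PET against TPA the PQQ median was 1.45 and the CO2 and formate median -0.96. Without a filter the other aromatic catabolism median for PET against TPA was -0.52. With all names that matched the fixed words, an alternative chosen after seeing the data, it was -0.44, and the PQQ median for EG against TPA was 1.56; both lists then hold more members. Under either rescaling 14 list medians, all within 0.15 of 0, differed in sign, 8 of them for PET against EG. Of 1800 values of named genes 25 moved, all toward 0 under the pseudocount of 10 and in 16 genes of low RPKM in at least 1 library. The unknown depth leaves the error of low values open, and the rounding alone limits them as described above.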

Other observations

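The tests of explanations and 12 gene lists in this part were chosen after the values were seen, while the flagella and chemotaxis list, the ribosomal protein list and both rescalings had been fixed earlier. On EG, most genes of methanol and formaldehyde oxidation through tetrahydromethanopterin, a carrier of one-carbon units, were higher than on the other carbon sources. Of 10 such genes, 9 were at least 2-fold higher on EG than on TPA and none was 2-fold lower (median 2.44), and 7 were 2-fold lower on PET than on EG (median -1.29). The formaldehyde-activating enzyme gene ISF6_1714 was at 1348 RPKM on EG, 266 on PET and 118 on TPA, and the methanol dehydrogenase large subunit gene ISF6_1713 was at 156 on PET and 67 on TPA, with a log2 ratio of 3.20 for EG against TPA. Between PET and TPA the same list had a median of 1.05, with 5 genes 2-fold higher on PET. Of 19 genes annotated for molybdenum hydroxylases of the carbon monoxide dehydrogenase type, 7 were at least 4-fold higher on EG and on PET than on TPA, in the run from ISF6_2773 to ISF6_2779. The list medians were 0.35 for PET against TPA, -0.24 for PET against EG and 0.13 for EG against TPA. In the list of 6 lactate genes, with medians of 0.00, -0.01 and -0.14 in that order, the permease and dehydrogenase genes ISF6_1310 and ISF6_1311 alone passed 2-fold, being higher on EG than on both others.

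Several sulfate uptake genes were low on TPA, with CysT (ISF6_3813) at 25 RPKM on TPA, 207 on PET and 143 on EG and CysP (ISF6_3802) at 50, 302 and 257. Of 18 sulfate and cysteine genes, 8 were at least 2-fold higher on PET than on TPA (median 0.63) and 1 higher on PET than on EG (median 0.36), and the EG against TPA median was 0.10. Pyruvate dehydrogenase E1 (ISF6_1478) was at 833 RPKM on TPA, 321 on PET and 161 on EG, and 3 of the 5 genes of the complex were 2-fold lower on PET than on TPA (median -1.37). The medians of the complex were 0.65 for PET against EG and -2.04 for EG against TPA. Phenylalanine-4-hydroxylase (ISF6_3026) was at 137 RPKM on TPA, 28 on PET and 25 on EG, 1 of 3 neighbours among 11 phenylalanine and tyrosine breakdown genes that were 4-fold lower on both (medians -0.22 for PET against TPA, 0.00 for PET against EG and -0.33 for EG against TPA). Of 51 branched-chain amino acid transport genes, 13 were 2-fold lower on PET than on TPA and 13 lower than on EG (medians -0.42 and -0.35), and the EG against TPA median was -0.12. Of 25 cyclic di-GMP genes, 13 were 2-fold lower on PET than on TPA and 12 lower than on EG (medians -1.02 and -0.67, and -0.29 for EG against TPA), such as ISF6_4266 at 16 RPKM on PET, 139 on TPA and 65 on EG. Of 58 genes of multidrug, metal and other efflux, 6 were 2-fold higher and 4 lower on PET than on TPA, and 6 were higher and none lower than on EG. The medians were 0.20 for PET against TPA, 0.21 for PET against EG and -0.05 for EG against TPA. None of 24 aminoacyl-tRNA synthetase genes passed 2-fold (medians 0.26, 0.03 and 0.24 for PET against TPA, PET against EG and EG against TPA). The 9 photosynthesis genes had medians of 0.26, 0.66 and -0.39 in the same order, with 2 past 2-fold for PET against EG. Median-of-ratios rescaling shifts PET against EG by -0.15, so medians smaller than that have no settled direction.

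Flagella and chemotaxis genes were lower on PET than on both monomers, with medians of -1.84 and -1.60. Scaling of the libraries does not account for this, since the highest of the 4 medians under both rescalings was -1.59, and 1 factor per library acts on all genes alike. Slower growth on PET was looked for in ribosomal protein genes, whose lower median was -0.077 (PET against TPA or EG), but a difference in growth stage that leaves those genes in place stays open. With 1 culture each, carbon source, contact with a film and growth stage cannot be told apart, and lower motility on film may at most be put forward as a hypothesis.

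The PET library held both terephthalate transcripts and the alcohol oxidation transcripts that were low on TPA. A mixture of RNA from the other 2 cultures could give such a library, but each gene would then lie between its TPA and EG levels. Of 75 flagella and chemotaxis genes, 67 were at least 2-fold below both on PET, which argues against a library made only of such a mixture. These genes cannot decide whether part of the RNA, carried over from the TPA culture, gave the terephthalate transcripts. Their median log2 ratio of PET against TPA, -1.84, lay above the -2.08 of the terephthalate list, so a share of that size stays possible. The release of both monomers from the film is the biological explanation the design gives, and it was not tested.

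The benzoyl-CoA genes ISF6_2817 to ISF6_2822 were higher on both monomers than on PET, although terephthalate genes were low on EG. Carry-over of TPA-culture RNA into the EG library would give both sets the same share of their TPA level. The EG level was at least 42.8% of the TPA level in these 6 genes (median 84.7%) and at most 1.99% in the 7 genes from ISF6_0226 to ISF6_0232. The 6 genes were chosen as a run lower on PET than on EG, so their high EG share was partly set by that choice. Their neighbours ISF6_2811 to ISF6_2816 had lower log2 ratios of EG against TPA, from -2.62 to -2.22. These still lay above those of ISF6_0226 to ISF6_0232, at most -5.34, which argues against carry-over as the source of the benzoate region transcripts on EG. Scaling does not account for the low PET values, since the highest median under both rescalings was -3.46. A carbon source effect and a difference between single cultures both remain open, and neither was tested. A list of 20 genes with box or benzoate names had medians of -1.74 for PET against TPA, -0.06 for PET against EG and -0.23 for EG against TPA. It also held 4-hydroxybenzoyl-CoA thioesterase genes such as ISF6_2875 (0.16, -0.02 and 0.19 in that order). Its medians therefore do not describe the box pathway alone.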
